A study of Caenorhabditis elegans with 24 samples.

How the data were processed

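Total RNA of whole day-1 adult worms grown at 20C was extracted with TRIZOL and made into small RNA libraries with the NEBNext kit, per the labels' protocols. The strain label is WT. The 24 samples form 8 groups of 3 by their group label: Control, P0 RNAi, and control RNAi and 2nd trigger in F1, F2 and F3. The labels number the replicates within each group and do not say whether replicates were separate cultures.

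The deposited values are raw read counts per gene, 1 set per sample, with 21965 gene features and 5 tally lines. The submitters' processing notes name cutadapt, FastQC, HTSeq, DESeq2 and the genome build ce10, without versions. The aligner, its treatment of reads with several hits, the strand setting of the counting and the gene annotation are not given in the sources used here. The tally lines stayed out of library sizes and tests. They held 31.8% to 44.9% of reads counted to no feature, 6.51% to 10.5% not aligned and 0.116% to 0.144% ambiguous, and 2 of them were 0 in every library, those for low mapping quality and for several alignments. Reads with several hits may therefore have been placed or dropped before counting, and genes with near-identical copies are uncertain. The deposited counts hold no read lengths, so 22G, 26G and 21U classes were not separated. The 20 leading genes took 13.4% to 27.1% of gene counts per library.

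The counts appear to be taken antisense to genes. Vitellogenin genes, whose mRNA is abundant in adults, held 0.0134% of counts. Genes with a microRNA on their opposite strand had a median of 7052 counts over all libraries (23 genes), against 1757.5 for genes with a microRNA on the same strand (66 genes). Y62F5A.9, which spans 7 microRNAs on the opposite strand, took 2.73% to 15.3% of gene counts. Because no strand setting is given, overlapping and antisense genes are uncertain.

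Gene names are those of the counts. The reference used is WBcel235, not ce10, so it gave names, gene types and overlaps only and no coordinates are printed. Of 21965 names 19055 matched it (16959 directly), and 19023 of those were protein coding. Another 6 names look like dates. MicroRNA, piRNA and structural RNA genes are not analysed here, though lists for them had been fixed. No column of another series was used.

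The main test was edgeR's quasi-likelihood F-test (edgeR 4.0.16, R 4.3.3) with TMM scaling, filterByExpr on the 8 groups (11091 genes tested) and all 24 libraries in 1 fit with a mean per group, so that all groups share 1 estimate of the spread. Benjamini-Hochberg adjusted p under 0.05 over the genes tested counts as called. There were 10 comparisons of 2 groups: P0 RNAi and each later group against Control, and 2nd trigger against control RNAi in each generation. The mean 2nd trigger effect, the difference of that effect between generations and any difference among the 8 groups were tested in the same fit. Log2 fold changes come with their standard errors.

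Gene lists were tested with camera (limma 3.58.1) on voom log-CPM with a preset correlation of 0.01, and again with an estimated correlation. Benjamini-Hochberg adjustment ran over the lists of a comparison with at least 3 tested members, 23 of the 26 fixed. These are exogenous RNAi and dsRNA import machinery, mutator complex and RNA-dependent RNA polymerases, ERI/26G pathway, Argonautes, nuclear RNAi inheritance and H3K9 chromatin, germ granule proteins, ERGO-1 class targets, spermatogenesis genes, F-box and MATH/BTB families, CSR-1 class germline genes, histones, ribosomal proteins, collagens and cuticle, vitellogenins, stress and heat shock, intracellular pathogen response, genes that lend sequence to germline reporters, and markers of intestine, muscle, neurons, hypodermis, sperm, and oocyte and embryo. The nuclear RNAi and H3K9 list also holds other chromatin genes, among them rbr-2, mes-2 and met-1, so it is a mixed list. Some genes stand in several lists. Nearly all genes of the sperm list also stand in the spermatogenesis list. The oocyte list and the list of genes that lend sequence to germline reporters share genes with the CSR-1 class list. The fry test (limma) asked whether the genes called in P0 RNAi moved, on balance, one way in other contrasts. It rotates residuals and is neither exact nor a permutation test, so with 3 libraries per group its direction is given, and its p only as adjusted over the 4 contrasts within lineages. For a gene at 0 in all libraries of a group the fitted change is no bound, and list medians were computed also with the floor of 3 counts per library in its place.

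The genes named in each comparison follow a rule: the 6 largest positive and 6 largest negative log2 fold changes among called genes whose groups do not overlap, the 3 smallest p-values, up to 6 called members of each machinery or reporter list by smallest p, up to 3 of each other list, and met-2, hrde-1, sid-1 and rde-1 throughout. For the 3 tests over several groups the 6 smallest p-values were taken. The text gives a selection of these. The groups, tests, lists, naming rule and the settings listed first below were fixed before the data were examined.

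Replicate libraries were compared by a chi-square of their counts over genes, which gave 2.24 to 46.9 per degree of freedom, so none was a repeat of another. Because comparisons against Control share its libraries, 20 simulations with no effect in any group gave the chance correlation, covariance and number of genes shared in the same direction, the last both at the threshold and with as many genes by smallest p as the real comparisons called. The simulations leave out real effects, and the number expected of independent lists leaves out the shared libraries. Other splits of the libraries were refitted, all 10 for 3 against 3 libraries and 100 drawn ones for the tests over several groups.

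The settings fixed beforehand were DESeq2's size factors or total counts in place of TMM, DESeq2 1.42.0 in place of edgeR, no filter on low counts, a filter at 10 CPM in 3 libraries, only the 6 libraries compared, the replicate number as a block, and leaving out each library. Alternatives chosen after seeing the data were thinning every library to 601832 counts, F1 2nd trigger from replicate 3 alone, with that library assumed to vary like those of the other groups, and removing Y62F5A.9.

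The scripts were tested on counts simulated for 11091 genes with 200 changed. For P0 RNAi against Control the test recovered 46.3%, 61.2% and 84.8% of genes changed 1.5-fold, 2-fold and 4-fold, with 11 false calls (7.91% of calls). For F1 2nd trigger against F1 control RNAi it recovered 34.3%, 67.2% and 86.4%, with 7 false calls (5.3%), and for F3 2nd trigger against F3 control RNAi 31.3%, 73.1% and 92.4%, with 4 false calls (2.96%). The changed list was called and 0 of 20 random lists were called in each of these simulations. Random lists do not stand for lists whose genes vary together, so this gives no rate of false calls for the fixed lists. In the data 68 lists were called with the preset correlation and 4 with an estimated one. Tables were read with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1, and figures drawn with matplotlib 3.10.9.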

Results

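Small RNAs were sequenced from whole day-1 adults of Caenorhabditis elegans, a nematode in which double-stranded RNA (dsRNA) taken up with food silences matching genes and in which silencing can pass to descendants through small RNAs. The 24 libraries fell into 8 groups of 3. Control worms were fed bacteria with an empty vector and never met dsRNA, and the labels give no generation for them. P0 RNAi worms ate dsRNA against gfp, the gene of a fluorescent reporter. Their F1, F2 and F3 descendants on empty-vector bacteria are called F1, F2 and F3 control RNAi here. A second lineage, also descended from worms that ate dsRNA against gfp, ate dsRNA against mCherry, an unrelated reporter gene, in F1. It then returned to empty-vector bacteria, which gives F1, F2 and F3 2nd trigger. This lineage thus met both triggers. The series set out to examine how a second exposure bears on small RNA inheritance. Values are small RNA reads counted to each gene, so they are not levels of the gene's mRNA, and reads of gfp and mCherry were not analysed here.

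Depth ranged from 601832 to 41811092 reads counted to genes, a 69.5-fold range, with a median of 6598880. The shallowest libraries were F1 2nd trigger replicates 1 (978218 counts) and 2 (601832 counts), and the deepest were P0 RNAi replicate 3 (41811092) and F2 2nd trigger replicate 2 (38898868). The floor of 3 counts was 4.98 CPM in the shallowest library and 0.0718 CPM in the deepest. For these floors and the intervals that follow, CPM is counts scaled to the library's gene counts. CPM means of genes given further on carry the TMM scaling as well and rest on the genes tested. A gene at 10 CPM rested on 6 counts in the shallowest library (exact 95% Poisson interval 3.66 to 21.7 CPM) and on 418 in the deepest (9.06 to 11.0 CPM). These intervals and floors cover counting error only. Nothing in the labels says that replicates came from separate cultures, so p-values measure only the spread between these samples.

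**Figure D1:**
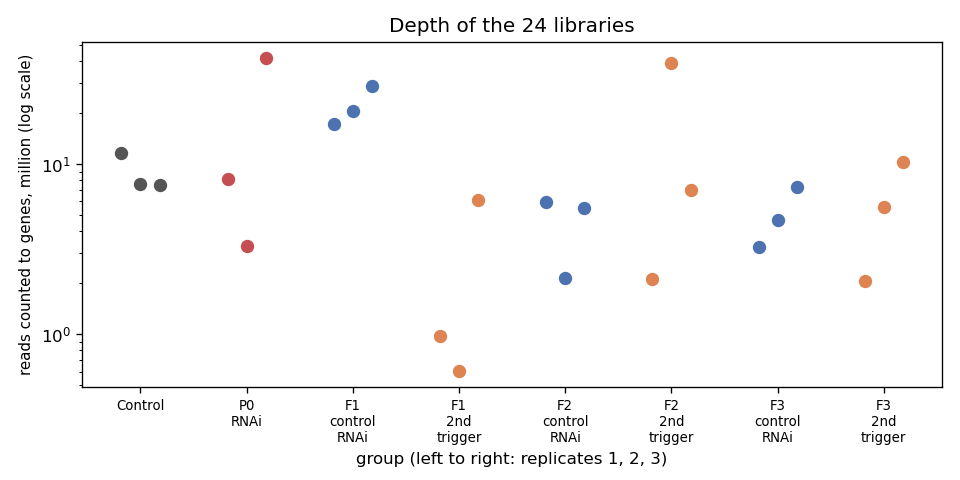
Reads counted to genes in each library, on a log axis, with 1 point per library and the replicates of each group from left to right. The 24 libraries span 601832 to 41811092 reads, and the lowest points are F1 2nd trigger replicates 1 (978218) and 2 (601832).

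Of 11091 genes tested, 7235 differed among the 8 groups at an adjusted p under 0.05 by edgeR's quasi-likelihood F-test. The smallest p-values belonged to gst-15 (a glutathione S-transferase), nhr-64 (a nuclear hormone receptor), asna-2, mab-5 (a Hox gene), unc-17 (the vesicular acetylcholine transporter) and K03H6.5, with edgeR adjusted p = 1.99e-14 for gst-15 and 2.12e-13 for K03H6.5. Reads of unc-17 were at 69.0 ± 3.97 CPM (mean ± SD, n = 3 here and for every CPM mean given) in Control and at 359 ± 4.61 and 369 ± 49.1 CPM in F3 control RNAi and F3 2nd trigger. The leading principal component held 27.2% of the variance and the next 14.1%. On the first, F1 2nd trigger replicates 1 and 2, the shallowest libraries, lay apart at -72.6 and -101, with replicate 3 of that group at -21.3 and the other libraries between -26.7 and 32.8. The plot of called genes gives the calls of the 10 comparisons of 2 groups.

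**Figure D2:**
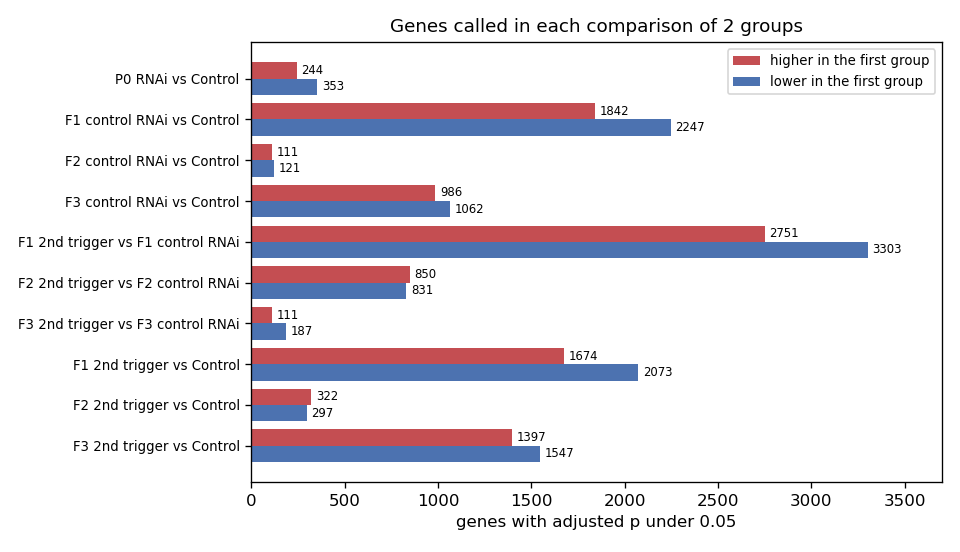
Number of genes with an adjusted p under 0.05 by edgeR's quasi-likelihood test in each comparison of 2 groups, with bars for genes higher and lower in the first-named group. The longest bars are the 2751 higher and 3303 lower genes of F1 2nd trigger against F1 control RNAi.

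Some genes of RNA interference were followed in every comparison. Reads of hrde-1, a germline nuclear Argonaute listed under its other name wago-9, did not pass the threshold in any of the 10 comparisons, with log2 fold changes from -0.14 to 0.13. Reads of met-2, a histone H3 lysine 9 methyltransferase, passed it in 3 comparisons, all with an F1 group, and reads of sid-1, the dsRNA channel, in 2, both with F1 2nd trigger (log2 -0.65 against F1 control RNAi and -0.48 against Control).

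P0 RNAi against Control asks what changed in the worms that ate dsRNA. Reads of cdh-1, a cadherin gene, were at 340 ± 41.3 CPM after RNAi and 82.8 ± 1.74 CPM in Control (log2 fold change 2.04, SE 0.13, edgeR adjusted p = 1.86e-10). Reads of ZC123.4 rose from 46.2 ± 2.33 to 283 ± 12.6 CPM (log2 2.62, SE 0.12, edgeR adjusted p = 5.35e-13), and this gene overlaps ZC123.1 on the opposite strand. Among the genes that fell were Y81G3A.1 (86.8 to 4.99 CPM, log2 -3.92), F42G4.6 (37.8 to 3.87 CPM, log2 -3.54) and C07G1.7 (54.1 to 10.0 CPM, log2 -2.64). In all, 597 of 11091 genes passed the threshold, 244 higher and 353 lower, and 138 of them changed at least 2-fold.

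Several gene groups moved in P0 RNAi. All 6 vitellogenin genes, which encode yolk proteins, were tested, and 2 rose over all genes (5 when adjusted over the list alone), with a median log2 of 0.72 (camera adjusted p = 0.00115; adjusted p = 0.283 with an estimated correlation). Reads of vit-6 were at 52.4 ± 29.4 CPM against 18.1 ± 3.34 CPM (log2 1.47). Of 14 stress and heat shock genes 5 rose, also 5 when adjusted over the list alone, with a median of 0.14 (camera adjusted p = 0.00557; adjusted p = 0.199 with an estimated correlation). The small heat shock genes hsp-16.1 (68.5 against 38.7 CPM) and hsp-16.48 (91.6 against 46.4 CPM) were among them, and near-identical copies can share reads. Of 32 collagen and cuticle genes 8 fell, also 8 when adjusted over the list alone, with a median of -0.32 (camera adjusted p = 0.00128; adjusted p = 0.199 with an estimated correlation). Reads of col-38 were at 72.9 ± 4.76 CPM against 162 ± 8.71 CPM (log2 -1.15). Of 3 intracellular pathogen response genes 1 rose, also 1 when adjusted over the list alone, with a median of 0.70 (camera adjusted p = 0.0273; adjusted p = 0.199 with an estimated correlation, and 0.0784 with F1 2nd trigger reduced to replicate 3). That member was skr-3, a Skp1-related gene, at 13.1 against 4.74 CPM.

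Another 7 lists passed camera's threshold in P0 RNAi, each lost without at least 1 library. They were F-box and MATH/BTB families (6 higher and 19 lower of 322, or 6 and 24 when adjusted over the list alone, median -0.11), CSR-1 class germline genes (2 higher of 41 under both adjustments, median 0.10) and histones (1 higher and 1 lower of 71, or 0 and 1 over the list alone, median -0.17). The others were germ granule proteins (0 of 14, median 0.08), ERGO-1 class targets (1 lower of 30, median -0.20), spermatogenesis genes (1 lower of 25, median -0.30) and reporter-donor genes (0 of 18, median 0.09), with the same counts over the list alone. Their camera adjusted p-values of 0.00249 to 0.0475 became 0.297 to 0.562 as adjusted p with an estimated correlation. Without Control replicate 3 all but histones were lost (camera adjusted p = 0.0558 to 0.714), and without P0 RNAi replicate 3 all but CSR-1 class genes (0.0636 to 0.475). Germ granule, ERGO-1 class and reporter-donor genes were also lost without P0 RNAi replicate 1 (0.116, 0.354 and 0.0557). Histones were also lost without Control replicate 1 (0.108) or 2 (0.0738). With a filter at 10 CPM the F-box and CSR-1 class lists were called and the others were not (0.0616 to 0.158).

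The number of P0 calls rested partly on single libraries: it was 357 without Control replicate 3 and 326 without P0 RNAi replicate 1. Total-count scaling gave 304 higher and 241 lower genes in place of 244 and 353.

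F1 control RNAi against Control asks what differed in the first generation after the exposure had ended. Reads of the list for nuclear RNAi and H3K9 chromatin fell as a group. It is a mixed list that also holds other chromatin genes, here and wherever it is named below. Reads of set-26, a SET domain gene, were at 198 ± 12 CPM against 415 ± 55.8 CPM (log2 -1.07, SE 0.12, edgeR adjusted p = 4.7e-07), and met-2 was at 159 against 208 CPM (log2 -0.38, SE 0.09, edgeR adjusted p = 0.00221). Of the 23 genes of that list 1 rose and 14 fell (1 and 15 when adjusted over the list alone), with a median of -0.38 (camera adjusted p = 0.00012; adjusted p = 0.112 with an estimated correlation). Reads of CSR-1 class germline genes fell for 20 of 41 members (22 when adjusted over the list alone), with a median of -0.24 (camera adjusted p = 6.18e-05; adjusted p = 0.112 with an estimated correlation). Among them, klp-7, a kinesin-13 gene, fell from 1010 ± 181 to 505 ± 34.1 CPM and puf-11, a PUF family gene, by a log2 change of -0.94. Ribosomal protein genes had 1 member higher and 50 lower of 79 (1 and 55 when adjusted over the list alone), with a median of -0.46 (camera adjusted p = 8.34e-11; adjusted p = 0.197 with an estimated correlation).

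Reads of the vitellogenin, F-box and neuronal lists rose in F1 control RNAi. All 6 vitellogenin genes rose, also 6 when adjusted over the list alone, with a median of 1.57 (camera adjusted p = 6.18e-05; adjusted p = 0.112 with an estimated correlation), and vit-6 was at 63.7 ± 12 CPM (log2 1.83, SE 0.30, edgeR adjusted p = 6.22e-05). In the F-box and MATH/BTB families, large gene families of substrate adaptors for protein degradation, 125 members rose and 18 fell of 322 (133 and 19 when adjusted over the list alone), with a median of 0.34 (camera adjusted p = 4.62e-08; adjusted p = 0.112 with an estimated correlation). Reads of fbxa-192 were at 1440 ± 23.4 CPM against 451 ± 44.4 CPM, and members of such families can share reads. Of 28 neuronal genes 9 rose and 2 fell (10 and 3 when adjusted over the list alone), with a median of 0.42 (camera adjusted p = 0.0218; adjusted p = 0.112 with an estimated correlation). Reads of unc-17 were at 130 ± 17.8 CPM and those of rab-3, a synaptic vesicle GTPase gene that overlaps damt-1, at 21.7 against 11.0 CPM. The share of reads on Y62F5A.9, which holds the mir-35 family on its opposite strand, was 12.8% ± 2.22 in F1 control RNAi and 8.16% ± 3.08 in Control.

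Sperm-linked and germ granule lists fell in F1 control RNAi. The sperm and spermatogenesis lists share most of their genes and are not separate results. Of 22 sperm genes 1 rose and 8 fell (1 and 9 when adjusted over the list alone), with a median of -1.31 (camera adjusted p = 0.0104; adjusted p = 0.112 with an estimated correlation). Of 25 spermatogenesis genes 1 rose and 9 fell (1 and 12 when adjusted over the list alone), with a median of -1.08 (camera adjusted p = 0.00865; adjusted p = 0.112 with an estimated correlation). The sperm-specific family genes ssp-16 (0.601 against 3.40 CPM) and ssp-34 (log2 -2.14) were low throughout. Of 14 germ granule genes 10 fell and 0 rose (10 and 1 when adjusted over the list alone), with a median of -0.31 (camera adjusted p = 0.00714; adjusted p = 0.251 with an estimated correlation), among them deps-1 (log2 -0.46) and meg-1 (log2 -0.63). Single genes of RNA interference fell too, by 0.44 on the log2 scale for rde-1, the Argonaute that takes up primary siRNAs (edgeR adjusted p = 0.00069), and by 0.52 for rrf-3, an RNA-dependent RNA polymerase. As lists, exogenous RNAi machinery (2 higher and 7 lower of 20), the mutator complex and RNA-dependent RNA polymerases (5 lower of 13) and Argonautes (2 higher and 10 lower of 23, camera adjusted p = 0.0777) did not pass.

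In F1 control RNAi 4089 genes passed the threshold, 1842 higher and 2247 lower, and total-count scaling gave 1138 higher and 3422 lower. Another 4 lists passed camera's threshold, and each was lost without at least 1 library. ERGO-1 class targets (11 higher and 1 lower of 30 under both adjustments, median 0.22) had camera adjusted p = 0.0218, and 0.0615 without Control replicate 2 or 0.102 without F1 control RNAi replicate 3. Collagens (7 lower of 32, or 6 when adjusted over the list alone, median -0.23) had camera adjusted p = 0.0218, and 0.06 without Control replicate 2. Intestinal genes (5 higher of 8 under both adjustments, median 1.07) had camera adjusted p = 0.0426, and 0.0869 without Control replicate 1 or 0.059 without F1 control RNAi replicate 3. Oocyte and embryo genes (6 lower of 17 under both adjustments, median -0.22) had camera adjusted p = 0.0373. Without Control replicates 1 and 2 that was 0.0778 and 0.0675, and without F1 control RNAi replicates 2 and 3 it was 0.0667 and 0.0616. Their adjusted p with an estimated correlation was 0.112 to 0.548. With a filter at 10 CPM the spermatogenesis, neuronal and oocyte lists were lost in this comparison (camera adjusted p = 0.894, 0.146 and 0.0698). The intestinal list was also lost without several libraries outside the comparison (camera adjusted p = 0.0532 to 0.071).

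F2 control RNAi against Control gave the fewest calls of the comparisons with Control. Reads of ZC123.4 (195 ± 7.44 CPM, log2 2.08, SE 0.12, edgeR adjusted p = 7.6e-11) and cdh-1 (304 ± 25.4 CPM, log2 1.88, SE 0.13, edgeR adjusted p = 1.51e-09) were again above Control. The receptor gene srh-71 rose from 1.40 to 15.0 CPM (log2 3.48) and nhr-64 from 21.9 to 66.9 CPM (log2 1.61). Reads of egl-21, a neuropeptide-processing carboxypeptidase, were at 39.5 against 21.6 CPM, and fbxa-216 fell from 50.6 to 16.0 CPM. Of 322 F-box and MATH/BTB genes 2 rose and 9 fell, also 2 and 9 when adjusted over the list alone, with a median of -0.15 (camera adjusted p = 0.000117; adjusted p = 0.549 with an estimated correlation). In all 232 genes passed, 111 higher and 121 lower; total-count scaling gave 111 and 79.

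The F2 control RNAi count was 145 without Control replicate 2, 101 without Control replicate 3, 132 without F2 control RNAi replicate 1 and 148 without F2 control RNAi replicate 2. Of the lists, ERGO-1 class targets (0 of 30, or 2 lower over the list alone, median -0.28), ribosomal protein genes (1 higher of 79 under both adjustments, median 0.12) and oocyte and embryo genes (1 higher of 17 under both, median 0.13) had camera adjusted p = 0.0121, 0.00785 and 0.0379, and an adjusted p of 0.549 each with an estimated correlation. Without Control replicate 3 these 3 lists had camera adjusted p = 0.541, 0.654 and 0.317, and without F2 control RNAi replicate 2 they had 0.0555, 0.144 and 0.211. The oocyte and embryo list was also lost without F3 control RNAi replicate 2 (0.0523).

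F3 control RNAi against Control showed 2 opposite shifts, in neuronal and in sperm genes. Reads of unc-17 were at 359 ± 4.61 CPM against 69.0 ± 3.97 CPM (log2 2.38, SE 0.13, edgeR adjusted p = 8.47e-12), rab-3 at 31.2 against 11.0 CPM and the neuropeptide-like gene nlp-24 at 29.3 against 9.71 CPM. Of 28 neuronal genes 6 rose and 0 fell (8 and 0 when adjusted over the list alone), with a median of 0.45 (camera adjusted p = 0.000293; adjusted p = 0.00681 with an estimated correlation). Of 22 sperm genes 8 fell and 0 rose (11 and 0 when adjusted over the list alone), with a median of -2.51 as fitted and -1.75 with genes at 0 in a whole group set to the floor of 3 counts per library (camera adjusted p = 2.48e-05; adjusted p = 0.0152 with an estimated correlation). Of 25 spermatogenesis genes 8 fell (11 when adjusted over the list alone), with a median of -2.02 as fitted and -1.36 at that floor (camera adjusted p = 9.95e-05; adjusted p = 0.0153 with an estimated correlation). Reads of ssp-16 were at 0.240 against 3.40 CPM and those of ssp-34 at 0.198 against 3.37 CPM, so these are low counts. The spermatogenesis call was lost with a filter at 10 CPM (camera adjusted p = 0.867), and the sperm list had too few genes to test there. Reads counted to no feature were at 39.5% in F3 control RNAi and 42.2% in F3 2nd trigger, with all libraries of both above the highest Control library (38%).

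Among other genes of F3 control RNAi, nhr-64 rose from 21.9 ± 2.62 to 125 ± 5.96 CPM (log2 2.51, SE 0.11, edgeR adjusted p = 1.56e-13) and ZC123.4 stood at 350 ± 48.2 CPM (log2 2.92). F-box genes went both ways, with fbxc-23 at 238 against 127 CPM and fbxc-42 at 33.9 against 85.0 CPM. Reads of wago-5, an Argonaute gene, fell from 3.10 to 0.381 CPM, and cgh-1, a germ granule helicase gene, rose by a log2 change of 0.43. In all 2048 genes passed the threshold, 986 higher and 1062 lower, and 697 changed at least 2-fold.

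F1 2nd trigger against F1 control RNAi asks what the second dsRNA changed in worms eating it, and gave the largest number of calls. Reads of the CSR-1 class, germ granule and oocyte lists rose. The oocyte list shares genes with both others, among them oma-1 and spn-4 with the CSR-1 class list, so these are not fully separate results. Reads of egg-4, a gene of the oocyte-to-embryo transition, were at 387 ± 17.3 CPM against 127 ± 11 CPM (log2 1.60, SE 0.09, edgeR adjusted p = 1.44e-11) and puf-3, a PUF family gene, at 185 ± 5.89 against 44.3 ± 0.657 CPM (log2 2.06, SE 0.11, edgeR adjusted p = 1.44e-11). Reads of jmjd-3.2, a Jumonji domain gene, fell from 536 ± 11 to 133 ± 25.2 CPM (log2 -2.0, SE 0.11, edgeR adjusted p = 1.44e-11). Of 41 CSR-1 class germline genes 29 rose and 2 fell, also 29 and 2 when adjusted over the list alone, with a median of 0.69 (camera adjusted p = 6.96e-09; adjusted p = 0.0652 with an estimated correlation). Of 14 germ granule genes 13 rose and 1 fell under both adjustments, with a median of 0.74 (camera adjusted p = 4.52e-06; adjusted p = 0.114 with an estimated correlation), among them glh-2 (log2 1.35) and meg-1 (log2 1.44). Of 17 oocyte and embryo genes 13 rose and 1 fell under both adjustments, with a median of 0.44 (camera adjusted p = 0.000242; adjusted p = 0.114 with an estimated correlation), among them rme-2, the yolk receptor, at 334 against 153 CPM.

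Reads of the nuclear RNAi and Argonaute lists rose in the same comparison, while other lists of RNA interference did not pass. Of 23 genes for nuclear RNAi and H3K9 chromatin 16 rose and 2 fell, also 16 and 2 when adjusted over the list alone, with a median of 0.60 (camera adjusted p = 4.29e-05; adjusted p = 0.114 with an estimated correlation). Reads of set-26 were at 586 ± 60.8 against 198 ± 12 CPM (log2 1.57) and met-2 at 301 ± 21.0 against 159 ± 3.49 CPM (log2 0.91, SE 0.10, edgeR adjusted p = 3.52e-08). Of 23 Argonaute genes 10 rose and 3 fell under both adjustments, with a median of 0.13 (camera adjusted p = 0.0452, and 0.085 with a filter at 10 CPM; adjusted p = 0.168 with an estimated correlation). Among them wago-1 stood at 156 against 74.5 CPM, csr-1 at 555 against 329 CPM and rde-1 at 113 against 56.9 CPM (log2 0.97, SE 0.10, edgeR adjusted p = 2.66e-08). Reads of dcr-1, which encodes Dicer, were at 144 against 75.5 CPM (log2 0.92, edgeR adjusted p = 1.86e-08) and rrf-3 at 163 against 74.8 CPM. The exogenous RNAi machinery (9 higher and 3 lower of 20, camera adjusted p = 0.0919) and the mutator complex and RNA-dependent RNA polymerases (8 higher and 1 lower of 13, camera adjusted p = 0.0729) did not pass as lists.

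F-box and ERGO-1 class genes fell. In the F-box and MATH/BTB families 13 members rose and 194 fell of 322 (14 and 197 when adjusted over the list alone), with a median of -0.74 (camera adjusted p = 7.98e-10; adjusted p = 0.0652 with an estimated correlation). Reads of fbxa-136 were at 71.2 against 183 CPM and those of fbxb-91 at 75.2 against 197 CPM. Of 30 ERGO-1 class targets, genes known for 26G small RNAs in oocytes and embryos, 21 fell (22 when adjusted over the list alone), with a median of -0.85 (camera adjusted p = 1.26e-05; adjusted p = 0.346 with an estimated correlation), among them E01G4.5, at 1860 against 5620 CPM. Ribosomal protein genes had 47 members higher and 5 lower of 79 under both adjustments, with a median of 0.56 (camera adjusted p = 4.74e-06; adjusted p = 0.375 with an estimated correlation). Of 18 genes that lend sequence to germline reporters 13 rose and 2 fell under both adjustments, with a median of 0.40 (camera adjusted p = 0.013, and 0.0505 with a filter at 10 CPM; adjusted p = 0.228 with an estimated correlation), among them tbb-2, a beta tubulin, at 148 against 40.7 CPM. In the stress list, which did not pass (camera adjusted p = 0.332), 2 genes rose and 8 fell of 14. Among them hsp-4, the chaperone BiP, stood at 124 against 41.4 CPM and hsp-16.1 at 4.89 against 22.3 CPM. The lower hsp-16.1 mean was near the floor of 3 counts in F1 2nd trigger replicates 1 (3.07 CPM) and 2 (4.98 CPM). These floors are given without TMM scaling. Lists of other tissues did not pass: vitellogenins had 4 of 6 lower (camera adjusted p = 0.175), neurons 1 higher and 9 lower of 28 (0.175), intestine 2 of 8 lower (0.431) and sperm 5 higher and 1 lower of 22 (0.175). Their mean scores against Control, in F1 2nd trigger and F1 control RNAi, were 0.387 and 1.54 for vitellogenins, -0.142 and 0.38 for neurons, 0.285 and 0.924 for intestine and -0.261 and -1.36 for sperm (mean log2 CPM). The share of reads on Y62F5A.9 was 5.16% ± 0.966 in F1 2nd trigger against 12.8% ± 2.22 in F1 control RNAi, and that of reads not aligned 9.93% ± 0.656 against 8.02% ± 0.582.

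In all 6054 genes passed in F1 2nd trigger against F1 control RNAi, 2751 higher and 3303 lower, and 2019 changed at least 2-fold. The scale mattered for the balance: the median of all genes was -0.163 on the log2 scale and 0.275 under total-count scaling, which gave 4271 higher and 1280 lower genes, so small changes have no firm direction. Replicates 1 and 2 of F1 2nd trigger lay apart on the leading principal component. With that group reduced to its deeper replicate 3, which is then assumed to vary like the libraries of the other groups, the count was 5004 genes and all 9 lists called here were called again, an alternative chosen after the depths were seen.

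**Figure D3:**
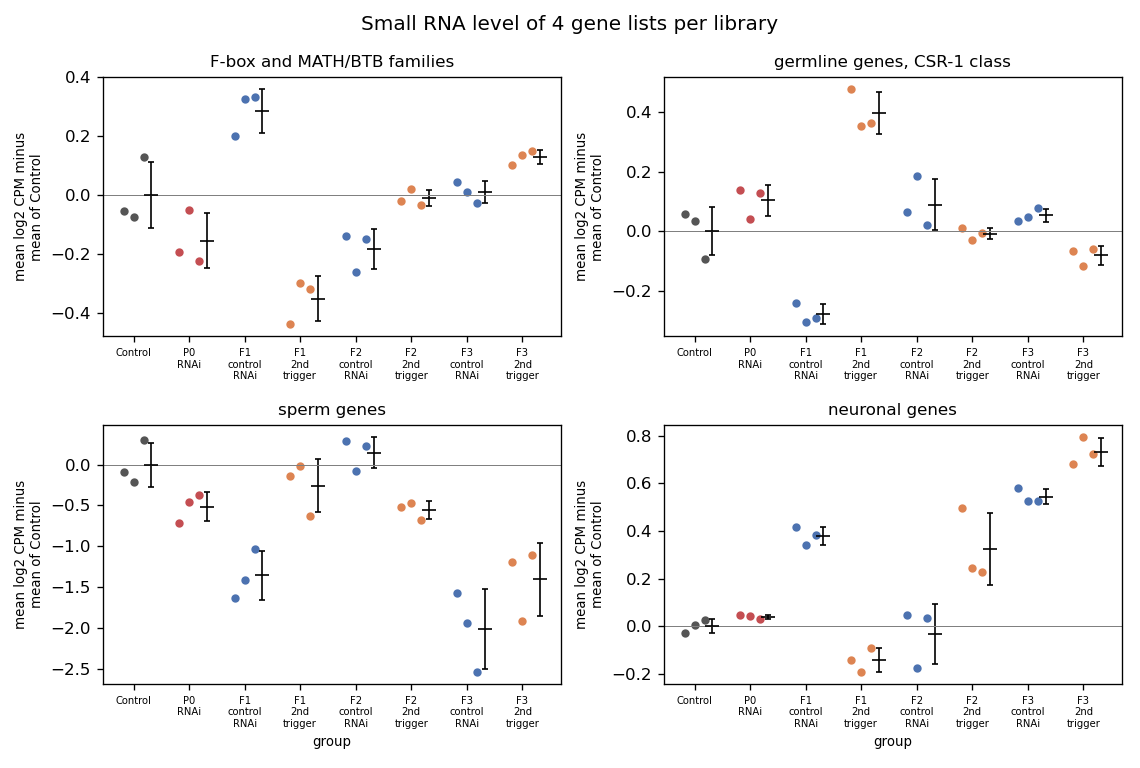
Mean log2 CPM of 4 gene lists in each library, minus the mean of the 3 Control libraries, with points for libraries and bars for the group mean ± SD (n = 3). F-box genes are highest and CSR-1 class genes lowest in F1 control RNAi, the reverse holds in F1 2nd trigger, and neuronal genes are highest in both F3 groups.

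F2 2nd trigger against F2 control RNAi compares the lineages 1 generation after the second dsRNA. Reads of ZC15.1 fell from 118 ± 2.16 to 28.3 ± 6.83 CPM (log2 -2.14, SE 0.13, edgeR adjusted p = 3.8e-10), aldo-1, an aldolase gene, to 32.6 ± 2.94 CPM (log2 -2.31, SE 0.15, edgeR adjusted p = 9.89e-10) and C07G1.7 from 64.2 ± 8.51 to 4.64 ± 1.16 CPM (log2 -3.71, SE 0.26, edgeR adjusted p = 1.32e-09). The histone gene his-66, whose copies can share reads, stood at 425 ± 224 against 35.5 ± 26.6 CPM (log2 3.46). Of 322 F-box and MATH/BTB genes 64 rose and 22 fell (74 and 25 when adjusted over the list alone), with a median of 0.25 (camera adjusted p = 0.00116; adjusted p = 0.482 with an estimated correlation). Members went both ways, with fbxb-22 at 74.9 against 38.5 CPM and fbxa-136 at 116 against 246 CPM. Of 23 genes for nuclear RNAi and H3K9 chromatin 3 fell, also 3 when adjusted over the list alone, with a median of -0.17 (camera adjusted p = 0.0183; adjusted p = 0.482 with an estimated correlation). Of 22 sperm genes 4 fell under both adjustments, with a median of -0.39 (camera adjusted p = 0.0327, and 0.053 without F2 control RNAi replicate 3; adjusted p = 0.482 with an estimated correlation). In all 1681 genes passed, 850 higher and 831 lower. The count was 925 without F2 2nd trigger replicate 2, and total-count scaling gave 388 higher and 1648 lower. Reads not aligned were at 9.57% (8.98% to 9.87%) in F2 2nd trigger and 7.59% (6.73% to 8.41%) in F2 control RNAi. Mean scores against Control were 0.323 and -0.032 for neurons, 0.853 and 0.321 for vitellogenins and 0.156 and 0.26 for intestine (mean log2 CPM). Whether the list shifts follow these differences was not tested.

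F3 2nd trigger against F3 control RNAi compares the lineages 2 generations after the second dsRNA. Reads of cdh-1 fell from 310 ± 34.0 to 142 ± 23.9 CPM (log2 -1.12, SE 0.13, edgeR adjusted p = 3.2e-05). Reads of srh-71 rose from 8.25 ± 5.33 to 45.9 ± 2.34 CPM (log2 2.51, SE 0.27, edgeR adjusted p = 2.49e-05), W03C9.6 from 23.3 ± 2.28 to 46.2 ± 2.44 CPM (log2 1.02) and fbxa-224 from 3.14 to 11.9 CPM (log2 1.84). Group shifts were small: nuclear RNAi and H3K9 chromatin (2 lower of 23, or 4 when adjusted over the list alone, median -0.17, camera adjusted p = 6.47e-05), germ granule proteins (1 lower of 14, or 3 over the list alone, median -0.18, camera adjusted p = 0.00202) and CSR-1 class genes (2 lower of 41, or 5 over the list alone, median -0.12, camera adjusted p = 0.000774) were lower. F-box and MATH/BTB genes were higher (5 higher and 2 lower of 322, or 4 and 2 over the list alone, median 0.12, camera adjusted p = 0.000497). With an estimated correlation these lists had an adjusted p of 0.193, 0.198, 0.193 and 0.193. In all 298 genes passed, 111 higher and 187 lower, and DESeq2's size factors gave 131 higher and 80 lower. Reads not aligned were at 6.86% (6.51% to 7.08%) in F3 2nd trigger and 7.76% (7.41% to 8.42%) in F3 control RNAi. Reads counted to no feature were at 42.2% and 39.5%. Mean scores against Control were 0.732 and 0.543 for neurons and -0.315 and -0.214 for vitellogenins (mean log2 CPM). Whether the list shifts follow these differences was not tested.

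The F3 difference between lineages rested on single libraries: without F3 control RNAi replicate 1 it gave 67 higher and 52 lower genes. The count was 112 and 54 without F3 control RNAi replicates 2 and 3, and 126, 79 and 138 without F3 2nd trigger replicates 1, 2 and 3. Another 7 lists passed camera's threshold at adjusted p = 0.0239 to 0.0369 and were lost with an estimated correlation (adjusted p = 0.193 to 0.69). These were exogenous RNAi machinery (1 lower of 20, or 2 over the list alone, median -0.11), the mutator complex and RNA-dependent RNA polymerases (1 lower of 13, or 4, median -0.13), ribosomal proteins (1 lower of 79, or 0, median -0.11), reporter-donor genes (1 lower of 18, or 1, median -0.13), oocyte and embryo genes (1 lower of 17, or 1, median -0.12), spermatogenesis genes (0 of 25, median 0.77 as fitted and 0.50 at the floor) and sperm genes (0 of 22, median 0.96 as fitted and 0.72 at the floor). All but the ribosomal list were lost without F3 control RNAi replicate 3 (camera adjusted p = 0.0877 to 0.241), and the ribosomal list without F3 control RNAi replicate 1 (0.0805) or 2 (0.255) or F3 2nd trigger replicate 2 (0.117). Leaving out F3 control RNAi replicate 2 gave 0.0528 to 0.255 for the lists it ended, and F3 2nd trigger replicates 1, 2 and 3 gave 0.064 to 0.0698, 0.0605 to 0.117 and 0.0761 to 0.23. The mutator and sperm lists were also lost without some libraries outside the comparison (0.0514 to 0.066). With a filter at 10 CPM none of the 7 was called (0.0977 to 0.198 for those tested; the sperm list had too few genes). With DESeq2's size factors the mutator and sperm lists were lost (0.0645 each), and the sperm list also with F1 2nd trigger reduced to replicate 3 (0.0687).

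F1 2nd trigger against Control sets the worms eating the second dsRNA beside worms never exposed. Reads of germ granule genes rose for 9 of 14 members (11 when adjusted over the list alone), with a median of 0.41 (camera adjusted p = 5.62e-06; adjusted p = 0.14 with an estimated correlation), and glh-2 stood at 156 against 76.3 CPM. Of 41 CSR-1 class genes 23 rose and 1 fell (24 and 2 when adjusted over the list alone), with a median of 0.39 (camera adjusted p = 1.32e-07; adjusted p = 0.14 with an estimated correlation), and cyb-2.2, a B-type cyclin gene, was at 96.7 against 35.1 CPM. Of 17 oocyte and embryo genes 8 rose and 1 fell (10 and 1 when adjusted over the list alone), with a median of 0.26 (camera adjusted p = 0.000284; adjusted p = 0.14 with an estimated correlation). In the F-box and MATH/BTB families 9 rose and 107 fell of 322 (10 and 114 when adjusted over the list alone), with a median of -0.39 as fitted and -0.38 at the floor (camera adjusted p = 5.62e-06; adjusted p = 0.14 with an estimated correlation), and fbxa-136 was at 71.2 ± 4.33 CPM (log2 -1.71, SE 0.09, edgeR adjusted p = 1.56e-11). Of 30 ERGO-1 class targets 17 fell under both adjustments, with a median of -0.59, and of -0.36 from F1 2nd trigger replicate 3 alone. With all libraries this list had camera adjusted p = 3.43e-05, and adjusted p = 0.346 with an estimated correlation.

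Of 23 genes for nuclear RNAi and H3K9 chromatin 11 rose and 1 fell against Control (13 and 1 when adjusted over the list alone), with a median of 0.26 (camera adjusted p = 0.00858, and 0.0787 from replicate 3 alone; adjusted p = 0.318 with an estimated correlation). Reads of dcr-1 (log2 0.63), rde-1 (log2 0.53) and met-2 (log2 0.53) rose. The small heat shock gene hsp-16.1 fell from 38.7 ± 1.41 to 4.89 ± 1.48 CPM (log2 -2.71, SE 0.22, edgeR adjusted p = 1.41e-08). Its lower mean was near the floor of 3 counts, without TMM scaling, in F1 2nd trigger replicates 1 (3.07 CPM) and 2 (4.98 CPM). The size of the drop is therefore uncertain. The stress list as a whole did not pass (2 higher and 8 lower of 14, camera adjusted p = 0.106). Exogenous RNAi machinery (6 higher and 3 lower of 20 under both adjustments, median 0.22), collagens (1 higher and 9 lower of 32 under both, median -0.42) and reporter-donor genes (7 higher of 18, or 7 higher and 1 lower over the list alone, median 0.27) had camera adjusted p = 0.0468, 0.0408 and 0.0125, and an adjusted p of 0.318, 0.318 and 0.304 with an estimated correlation. From replicate 3 alone they had 0.0983, 0.145 and 0.0829. The first of them was lost without Control replicates 1 or 2 (0.0511, 0.0591) or F1 2nd trigger replicates 1 or 2 (0.0663, 0.0671), the next without Control replicates 1 or 2 (0.0548, 0.0802) or F1 2nd trigger replicates 1 or 2 (0.0663, 0.0653), and reporter-donor genes without F1 2nd trigger replicate 1 (0.0653). The exogenous RNAi and collagen lists were also lost without some libraries outside the comparison (0.053 to 0.0584), and the first with a filter at 10 CPM (0.12). In all 3747 genes passed, 1674 higher and 2073 lower; DESeq2's size factors gave 2028 higher and 1713 lower, and total-count scaling gave 3013 higher genes, 79.1% of its calls, and moved the median of all genes from -0.084 to 0.189.

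F2 2nd trigger against Control gave 619 genes, 322 higher and 297 lower. Reads of Y55D5A.1, which overlaps Y55D5A.4, rose from 2.05 to 76.7 ± 12.4 CPM (log2 5.23, SE 0.34, edgeR adjusted p = 5.54e-10), srh-71 from 1.40 to 34.2 CPM (log2 4.64) and F23B12.4 from 23.5 to 116 CPM (log2 2.31). Vitellogenins were the list that passed: 1 of 6 rose (5 when adjusted over the list alone), with a median of 0.93 (camera adjusted p = 0.000162; adjusted p = 0.382 with an estimated correlation), and vit-6 was at 46.8 against 18.1 CPM (log2 1.46, edgeR adjusted p = 0.00548). The count was 384 and 400 without Control replicates 1 and 2 and 330 without F2 2nd trigger replicate 2. Without Control replicate 3 it gave 215 higher and 187 lower genes. Total-count scaling gave 171 higher and 485 lower.

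F3 2nd trigger against Control gave 2944 genes, 1397 higher and 1547 lower. Reads of neuronal genes rose for 14 of 28 members (15 when adjusted over the list alone), with a median of 0.72 (camera adjusted p = 6.3e-06; adjusted p = 0.000727 with an estimated correlation), led by unc-17 at 369 ± 49.1 CPM (log2 2.42, SE 0.13, edgeR adjusted p = 6e-12), nlp-24 at 34.3 against 9.71 CPM and rab-3 at 27.3 against 11.0 CPM. The Hox gene mab-5 rose from 16.7 ± 1.23 to 71.3 ± 6.11 CPM (log2 2.11, SE 0.11, edgeR adjusted p = 6e-12) and srh-71 from 1.40 ± 0.571 to 45.9 ± 2.34 CPM. Of 23 genes for nuclear RNAi and H3K9 chromatin 9 fell (12 when adjusted over the list alone), with a median of -0.24 (camera adjusted p = 0.000926; adjusted p = 0.35 with an estimated correlation), among them set-26 (234 ± 44.6 against 415 ± 55.8 CPM) and hpl-2, an HP1 homolog (log2 -0.75). Reads of prg-1, the Piwi Argonaute, were at 396 against 506 CPM. F-box and MATH/BTB genes had 70 higher and 32 lower of 322 (72 and 32 when adjusted over the list alone), with a median of 0.18 (camera adjusted p = 0.00947; adjusted p = 0.389 with an estimated correlation). Of 22 sperm genes 6 fell under both adjustments, with a median of -1.09 as fitted and -0.96 at the floor (camera adjusted p = 0.0209, and 0.06 without F3 2nd trigger replicate 2 or 0.0596 without P0 RNAi replicate 3; adjusted p = 0.35 with an estimated correlation). The count of genes was 1795 without F3 2nd trigger replicate 2. The balance depended on the scaling, with 1115 higher and 2320 lower by total counts and 1574 higher and 1179 lower by DESeq2's size factors.

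Across the 10 comparisons 68 of 230 list tests passed camera's threshold, and 4 held with an estimated correlation. These were the neuronal, sperm and spermatogenesis lists in F3 control RNAi and the neuronal list in F3 2nd trigger, each against Control. They are not 4 separate results, since all share the Control libraries and nearly all sperm genes also stand in the spermatogenesis list. With a filter at 10 CPM both neuronal calls held (camera adjusted p = 0.000252 and 0.000236). The spermatogenesis call was lost there, and the sperm list had too few genes to test. In 20 of the 68 the list means by library overlapped between the groups. Against Control these were collagens, F-box, CSR-1 class, germ granule, ERGO-1 class, histone and reporter-donor genes in P0 RNAi, ERGO-1 class in F1 and F2 control RNAi, ribosomal and oocyte genes in F2 control RNAi, collagens and reporter-donor genes in F1 2nd trigger, and F-box genes in F3 2nd trigger. Between lineages they were reporter-donor genes in F1, and the exogenous RNAi, spermatogenesis, sperm, ribosomal and reporter-donor lists in F3. With a filter at 10 CPM 43 of the 68 were called again, 18 were lost and 7 had too few genes to test. The genes of the ERI/26G pathway (10 tested; 5 higher and 3 lower in F1 2nd trigger against F1 control RNAi, camera adjusted p = 0.411), of body wall and pharyngeal muscle (6 tested; 1 higher and 2 lower, 0.519) and of the hypodermis (4 tested; 1 higher in F1 control RNAi against Control, 0.439) passed camera's threshold in none of the 10. None of the called lists changed the sign of its median between TMM, DESeq2's size factors and total-count scaling.

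ZC123.4 was above Control in all 7 other groups, with log2 fold changes from 2.08 to 2.92, and cdh-1 was among 33 genes at which the 3 Control libraries lay outside the range of the other 21. Other members were fbxa-192, fbxa-216, Y55D5A.1 and Y81G3A.1. The 33 are of 11091 genes tested, and chance gives that layout for 0.0988% of genes if all 24 libraries are exchangeable. The differences among groups go against that condition. The same count was 27 for F2 2nd trigger, 54 for P0 RNAi and 75 to 1741 for the other groups, so Control does not stand out by it.

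**Figure D4:**
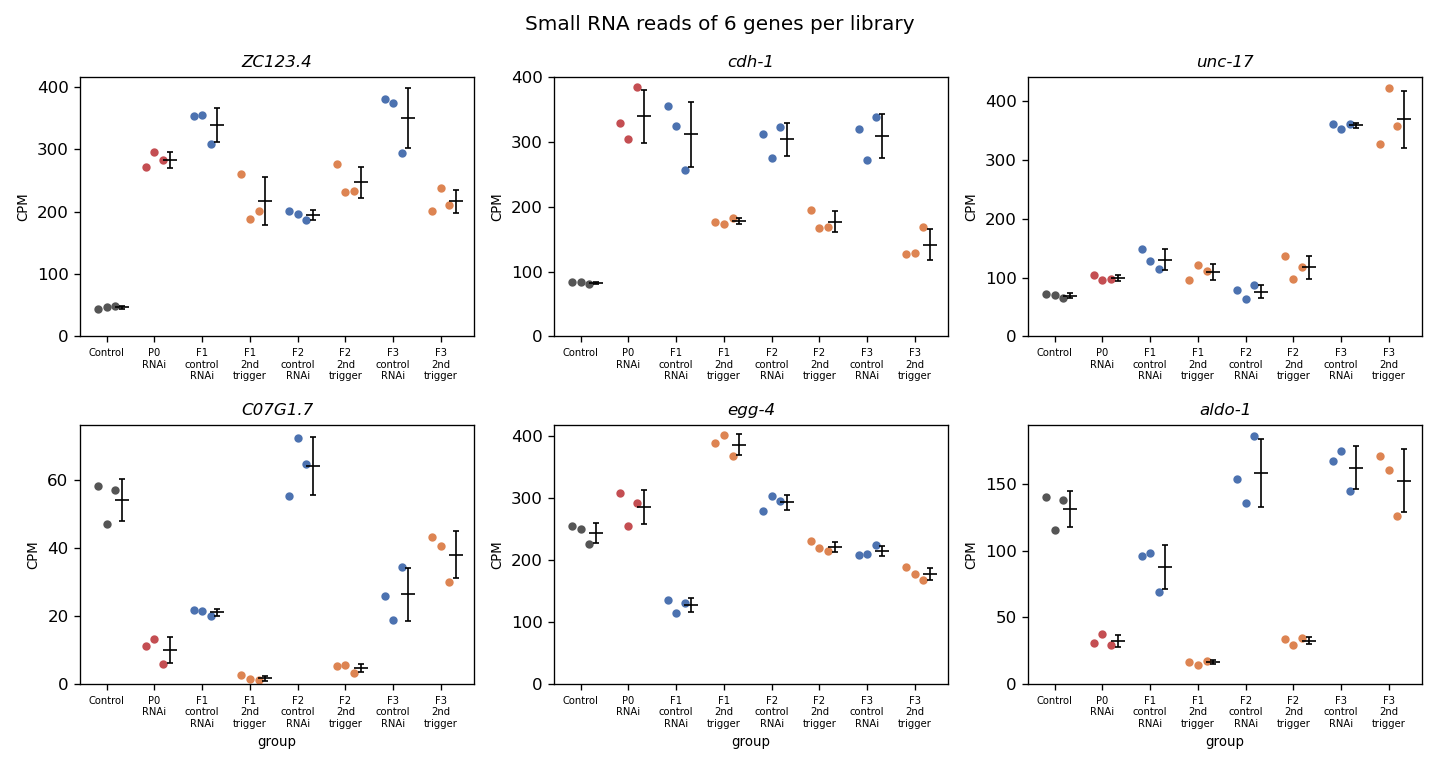
CPM of 6 genes in each library, with points for libraries and bars for the group mean ± SD (n = 3). Reads of ZC123.4 and cdh-1 are lowest in Control, those of unc-17 highest in both F3 groups, those of egg-4 lowest in F1 control RNAi, and those of C07G1.7 and aldo-1 lowest in F1 2nd trigger.

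The 2nd trigger effects differed between generations for 6018 genes by edgeR's F-test of the interaction. Reads of egg-4 changed by a log2 of 1.60 (SE 0.09) in F1, -0.41 (SE 0.08) in F2 and -0.27 (SE 0.09) in F3, with an edgeR adjusted p = 1.46e-10 for the difference. For jmjd-3.2 the changes were -2.0, 0.16 and 0.47, and for puf-3 2.06, -0.27 and -0.34. Across the 11091 genes, which are not independent replicates, the F1 and F2 effects had a Pearson correlation of -0.373. Of 1327 genes called in both, 1186 went opposite ways and 141 the same way, where independent lists give 459 and 458. The F1 and F3 effects had r = -0.0645, with 196 opposite and 56 the same (79.4 and 83.2 in independent lists). The F2 and F3 effects had r = -0.147 over all genes, while 93 shared calls went the same way and 42 opposite ways (22.5 and 22.7 in independent lists).

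The mean 2nd trigger effect over F1, F2 and F3 passed for 1081 genes, 498 higher and 583 lower, and 35 of them by at least 2-fold. The count was 654 with F1 2nd trigger reduced to replicate 3. Reads of cdh-1 were lower in each generation (log2 -0.81, -0.79 and -1.12; mean -0.91, SE 0.07, edgeR adjusted p = 2.57e-08). Those of aldo-1 were lower in F1 and F2 (log2 -2.38 and -2.31) and near the other lineage in F3 (-0.10, SE 0.14), as were those of C07G1.7 (-3.99, -3.71 and 0.46) and fbxa-136 (-1.35, -1.09 and 0.18). The balance of this count turned with the scaling: DESeq2's size factors gave 796 higher and 473 lower genes and total-count scaling 945 and 343.

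The responses to both exposures were compared between P0 RNAi against Control and F1 2nd trigger against F1 control RNAi, which share no library. Of 442 genes called in both, 56 rose in both, 187 fell in both and 199 went opposite ways, where independent lists give 60.5 and 105 for the first 2 counts. The number expected to go opposite ways was not computed. P0 genes were called more often than others in the second comparison (442 of 597, beside 54.6% of all genes). The excess of genes that fell in both is therefore no measure of a shared direction by itself. Of the 597 P0 genes, 53.9% had the same sign in both, and fry put their balance in the P0 direction. Across all genes r was -0.0126. This was not stable. The balance turned against the P0 direction without Control replicate 3 (46.5% with the same sign) or P0 RNAi replicate 3 (45.4%) and was even without P0 RNAi replicate 1 (50%). It was also less clear without Control replicate 2 (52.5%) or F1 control RNAi replicate 2 (50.9%).

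Persistence of the P0 response was measured against Control, which all these comparisons share. Of the 597 P0 genes 335 were called in the same direction in F1 control RNAi, 82 in F2 and 181 in F3 (112, 6.29 and 55.5 in independent lists), and 59, 14 and 118 in the opposite direction. In the 2nd trigger lineage the counts were 337, 169 and 161 (103, 16.5 and 80.0), with 39, 27 and 169 opposite. In 20 simulations with no effect at most 1 gene was shared at the threshold. Taking as many simulated genes by smallest p as were called gave on average 395, 60.8 and 251 in the same direction for the control RNAi lineage (at most 410, 80 and 271) and 309, 131 and 304 for the 2nd trigger lineage (at most 334, 148 and 318). The observed count lay above the highest of these in F2 control RNAi, F1 2nd trigger and F2 2nd trigger and below their mean in the other groups. In the opposite direction the simulations averaged 9.6, 0.15 and 4 genes and 16.1, 1.25 and 7.75, below the observed counts in all 6. The correlation of log2 fold changes with P0 was 0.493, 0.276 and 0.415 in the control RNAi lineage, beside 0.548, 0.461 and 0.477 in 20 simulated groups with no effect. In the 2nd trigger lineage it was 0.440, 0.522 and 0.247, beside 0.402, 0.508 and 0.485. The covariance above the simulated mean was 0.0791 in F1, 0.0063 in F2 and 0.0739 in F3 of the control RNAi lineage, and 0.0745, 0.051 and 0.0158 in the 2nd trigger lineage. In F2 control RNAi the covariance of 0.0472 lay below the highest simulated value of 0.0504, and leaving out 1 library moved the excess between 0.00241 (without F2 control RNAi replicate 1) and 0.0117 (without F2 control RNAi replicate 3). The F1 2nd trigger excess was 0.117 without replicate 3 of that group, and the F3 2nd trigger excess was 0.0212 to 0.0401 without any 1 library. The 3 Control libraries cannot be split into 2 sets of at least 2, so part of the excess may come from them.

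Within each lineage, which leaves the Control libraries out of the later contrast, the 597 P0 genes moved against their P0 direction after F1. Their median log2 change in the P0 direction was -0.235 from F1 to F2 and -0.215 from F1 to F3 in the control RNAi lineage, and -0.316 and -0.574 in the 2nd trigger lineage. The fry test gave Down each time, with adjusted p = 7.48e-09, 1.59e-09, 1.59e-09 and 1.55e-12 over the 4 contrasts (Benjamini-Hochberg). Both contrasts of a lineage subtract the same F1 libraries, so the 4 results are not independent. F1 control RNAi and F1 2nd trigger lay outside the range of all other libraries at 1140 and 1741 genes. A displaced F1 group alone could give Down in both contrasts, so these tests cannot show that the P0 response faded.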

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

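The tests chosen only after the result was seen were thinning to 1 depth for the F-box and CSR-1 class pattern, and the test of a displaced F1 control RNAi group.

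Effects of the 2nd trigger differed between generations for 6018 genes by edgeR's F-test of the interaction. In the 6 genes with the smallest p the F2 effect minus the F1 effect was -2.01 on the log2 scale for egg-4, 2.15 for jmjd-3.2, -2.34 for puf-3, -2.09 for mel-32, -1.79 for tkt-1 and -1.63 for mat-1. Outside the gene counts, reads not aligned averaged 9.93% in F1 2nd trigger (9.2% to 10.5%) and 9.57% in F2 2nd trigger (8.98% to 9.87%), above the highest Control library at 8.65%, while F3 2nd trigger, at 6.86% (6.51% to 7.08%), lay below the lowest at 7.60%. Reads counted to no feature averaged 39.5% in F3 control RNAi (38.7% to 40.2%) and 42.2% in F3 2nd trigger (40.2% to 44.9%), above the highest Control library at 38%.

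F-box and MATH/BTB genes were lower and CSR-1 class genes higher in F1 2nd trigger than in F1 control RNAi, a difference of -1.48 (SE 0.142) in the mean log2 CPM of the first list minus the second. Depth is argued against as the cause, since the difference was -1.25 (SE 0.0627) with every library thinned to 601832 counts. The score followed the log2 share of Y62F5A.9 within groups (Pearson r = 0.792, permutation p = 0.00029). Spearman rho was 0.83 (permutation p = 0.00038), and r was 0.79 without the 2 farthest libraries. Stage or embryo content could therefore have part in it. That slope predicts a difference of -0.32 (95% interval -0.456 to -0.184), so what Y62F5A.9 follows falls short of -1.48. The interval covers the error of the slope alone, and other markers of stage were not used, so stage as a whole is not bounded. A displaced F1 control RNAi group alone is argued against as well, since 3 of 3 F1 2nd trigger libraries (-3.40 to -2.96) lay below the 18 libraries of the other 6 groups (-2.79 to -2.05), while F1 control RNAi (-1.84 to -1.66) lay above them. A response to the second dsRNA stays open and was not tested apart from other differences between these groups.

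At 33 genes, ZC123.4 and cdh-1 among them, the 3 Control libraries lay outside the range of the other 21. The same count was 54 for P0 RNAi, 1140 and 1741 for F1 control RNAi and F1 2nd trigger, 113 and 27 for the F2 groups and 75 and 315 for the F3 groups. A batch or lineage difference special to Control had been set to be excluded if another group stood apart at more genes, but that bound was wrong, since those counts rest on the other groups' own effects. It cannot be told apart from the Control group itself, because the design holds 1 set of Control libraries. A dsRNA response that fades stays open: the median move of the 33 genes from F1 to F3 control RNAi, signed away from Control, was 0.202. Control generation and dsRNA exposure were not separated by the design as the labels give it.

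The 2nd trigger effects in F1 and F2 went opposite ways across genes (r = -0.373). Depth is argued against, since thinning every library gave r = -0.353, and -0.364 to -0.342 over 5 thinnings. An axis on which replicates of a group also differ stays open: the leading replicate axis of the 4 other groups had an absolute correlation of 0.214 with the F1 effect (0.0843 to 0.217 on leaving out a group). Biological differences between generations stay open as untested.

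Other splits of the libraries bear on the counts of genes. The 3 against 3 comparisons have 10 splits, too few for a share under 0.05, and in each 1 of the 10 splits, the real one, gave a count as large. The highest count of another split was 0 beside 597 in P0 RNAi, 4089 in F1 control RNAi, 232 in F2 control RNAi and 2048 in F3 control RNAi, each against Control. It was 0 beside 6054, 7 beside 1681 and 0 beside 298 for 2nd trigger against control RNAi in F1, F2 and F3, and 1 beside 3747, 0 beside 619 and 0 beside 2944 for 2nd trigger against Control. For any difference among the 8 groups 1 of 100 splits, the real one, gave 7235 genes (highest other 175). Libraries of a group thus resembled each other more than in random groupings. The labels do not say whether replicates were separate cultures. The splits therefore cannot tell a group effect from a culture or batch shared within a group. For the difference between generations 1 of 100 splits, the real one, gave as many as 6018 genes (highest other 4475). The split with 4475 keeps the F1 groups whole and exchanges F2 and F3 libraries. Such splits stand for no effect in any generation, not for equal effects, so they cannot decide whether the effects differ between generations. For the mean 2nd trigger effect 8 of 100 splits gave as many as 1081 genes, the highest 3693, so chance cannot be excluded. The 7 splits with more genes than the real one keep the F1 groups whole and exchange F2 and F3 libraries, which points to the large F1 difference as a structure of the samples.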

How the results depend on the processing

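Thinning, F1 2nd trigger from replicate 3 alone and removing Y62F5A.9 were chosen after the data were seen; all other settings were fixed beforehand. Of 7417 values of named genes under the settings fixed beforehand 6635 kept their side of the threshold, 778 lost it and 4 gained it. Among values called in the main fit 0 reversed their direction. For values called in neither fit no claim about direction is made. Of 1187 under added ones 1016 were kept, 166 lost and 5 reversed. Causes were not tested except where fewer reads, libraries or genes tested follow from the setting itself. In the shallowest library 2-fold changes of genes near 10 CPM were within counting error.

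With no filter on low counts F3 2nd trigger against F3 control RNAi gave 179 genes, 116 higher and 63 lower, beside 111 and 187 in the main fit. With only the 6 libraries compared P0 RNAi gave 379 and F2 control RNAi 120 against Control, and 2nd trigger against control RNAi gave 1011 in F2 and 161 in F3. The balance turned in F2 control RNAi, with 77 higher and 43 lower beside 111 and 121 in the main fit. Between lineages it turned to 498 and 513 in F2, beside 850 and 831, and to 90 and 71 in F3. Thinned to 601832 counts, which removes reads, the counts against Control were 136 in P0 RNAi, 908, 39 and 568 in F1, F2 and F3 control RNAi and 1844, 117 and 853 in F1, F2 and F3 2nd trigger, and 3300, 370 and 9 for 2nd trigger against control RNAi. Thinning turned the balance to 535 higher and 373 lower in F1 control RNAi, 21 and 18 in F2 control RNAi, 337 and 231 in F3 control RNAi and 595 and 258 in F3 2nd trigger, each against Control, and to 8 and 1 between lineages in F3. From replicate 3 alone F1 2nd trigger gave 2251 genes against Control and the mean effect 654. Reversed after thinning, with none called there, were rde-2 in F1 control RNAi against Control (log2 0.068), eri-1 in F1 2nd trigger against Control (-0.056), and rsd-2 (0.030), drh-1 (0.048) and ego-1 (0.031) in F3 2nd trigger against Control. Removing Y62F5A.9, run for the 10 comparisons of 2 groups, kept the side of all 573 values of named genes there.

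Leaving out each library gave 326 to 560 genes in P0 RNAi, 2958 to 4033, 101 to 182 and 1528 to 1738 in F1, F2 and F3 control RNAi and 2754 to 3416, 330 to 482 and 1795 to 2640 in F1, F2 and F3 2nd trigger, each against Control. For 2nd trigger against control RNAi it gave 4730 to 5772, 925 to 1616 and 54 to 138 in F1, F2 and F3, for the mean 752 to 1240, for the difference between generations 5253 to 6185, for any difference 6702 to 7438, and 63 to 76 called lists. Of 68 called lists 4 were called with an estimated correlation. A filter at 10 CPM gave 45 called lists, 43 of them among the 68; 18 of the 68 were lost and 7 had too few genes to test.

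For P0 RNAi against the F1 2nd trigger response, r was 0.001735 by DESeq2, 0.1622 with a filter at 10 CPM and -0.05754 with no filter (49.7% with the same sign), and -0.08876 to 0.0317 on leaving out a library. The persistence excess was 0.02802 with no filter and 0.01871 at 10 CPM in F2 control RNAi (0.00241 to 0.0117 on leaving out a library), and -0.008145 at 10 CPM in F3 2nd trigger.

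The replicate numbers do not pair the samples: deviations of same-numbered libraries correlated between -0.149 and 0.191 (median 0.021, 8 of 84 over 0.1), and 11 of 24 libraries were closest to their own number. With the number as a block the counts were 597 in P0 RNAi, 4089, 240 and 2043 in F1, F2 and F3 control RNAi, 3684, 591 and 2921 in the 2nd trigger groups against Control, 6014, 1635 and 266 between lineages, 1086 for the mean, 5958 for the difference between generations and 7156 for any difference. The block gave 65 called lists, and 4 of the 68 were not called: histones in P0 RNAi (camera adjusted p = 0.118), exogenous RNAi machinery (0.0501) and collagens (0.0533) in F1 2nd trigger, each against Control, and sperm genes in F2 2nd trigger against F2 control RNAi (0.0537).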

Other observations

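The genes below come from the same naming rule, no test was added for this part, and the last paragraph was chosen after its values were seen. Reads of rpl-42, a ribosomal protein gene, were below Control in P0 RNAi (log2 -1.13), F1 control RNAi (-1.69), F3 control RNAi (-2.88) and F3 2nd trigger (-1.63), while those of rpl-11.2 were above Control in P0 RNAi (0.71) and F2 control RNAi (0.78). Among histone genes the linker histone gene hil-4 fell in F1 control RNAi against Control (-0.78) and rose in F1 2nd trigger against F1 control RNAi (1.73). The intestinal proton pump gene vha-6 had log2 changes of 1.52 in F1 control RNAi against Control and -1.30 in F1 2nd trigger against F1 control RNAi. Among collagens col-60 (1.14) and col-99 (1.65) rose in F3 2nd trigger against Control, where 5 of 32 members rose and 0 fell and the list did not pass (camera adjusted p = 0.232).

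Reads of srh-71 were at 1.40 CPM in Control, 15.0 CPM in F2 control RNAi, 34.2 CPM in F2 2nd trigger and 45.9 CPM in F3 2nd trigger. Reads of nlp-36, which overlaps dars-1, were at 5.73 CPM in Control, 14.7 CPM in P0 RNAi, 15.6 CPM in F2 control RNAi and 34.4 CPM in F2 2nd trigger. The F-box gene fbxa-125 rose from 4.14 CPM in Control to 61.9 CPM in F1 2nd trigger (log2 3.97), and by log2 changes of 3.68 in F3 control RNAi, 3.96 in F2 2nd trigger and 3.79 in F3 2nd trigger.

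Reads of aldo-1 and C07G1.7 were lowest in P0 RNAi, F1 2nd trigger and F2 2nd trigger, an order read from the group means and not tested. Those of aldo-1 were at 131 CPM in Control, 32.3 CPM in P0 RNAi, 87.6 CPM in F1 control RNAi, 16.1 CPM in F1 2nd trigger and 32.6 CPM in F2 2nd trigger, and at 162 and 152 CPM in F3 control RNAi and F3 2nd trigger.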
